A study of Limosilactobacillus reuteri subsp. rodentium with 6 samples.

How the data were processed

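RNA from Limosilactobacillus reuteri was measured on 6 arrays of a custom Agilent design, each hybridised with a Cy3 and a Cy5 sample. Per the labels' protocols, stomach contents and scrapings of 6 to 8 mice were pooled for each RNA sample, mouse RNA was depleted from the stomach samples, cultures were sampled after 4 and 8 hours, and RNA was amplified before labelling. The labels name the culture strain 100-23 and, in the growth protocol, the strain given to the mice 100-23C. Groups were taken from the sample titles: stomach against log phase (2 arrays), stomach against stationary phase (2 arrays) and uninoculated stomach against log phase (2 arrays, with dyes exchanged between them). The design text calls the replicates independent biological replicates.

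Per the file headers, the authors quantified the scans with Agilent Feature Extraction, version 9.5.3.1 for the arrays of colonised mice and 9.5.1.1 for the uninoculated arrays, whereas the submitters' processing notes give 9.5.3.1. The 2 slides were read on scanners of different makes, so levels were not compared between them, and the 4 arrays of colonised mice share a slide. The deposited intensity columns hold the mean spot signal and median local background per channel as measured, and the processed signal. Per the file headers, the processed signal is detrended and dye-normalized within the array. The headers' code for the background subtraction method was 7 on the arrays of colonised mice and 6 on the uninoculated arrays. That step thus differed between the slides. The deposited log10 ratio is Cy5 over Cy3 of these processed signals. The deposited series table holds the same log10 values: 100% of the spots were equal (to within 1e-9) on 5 arrays, and equal with the sign turned on uninoculated replicate 1, so that both uninoculated columns run as uninoculated over log phase. The column medians of that table, on the log10 scale, were -0.0577, -0.0219, -0.0335 and -0.038 for the colonised arrays and -0.196 on both uninoculated arrays. The flags for outliers, saturation and signal above background are the scanner software's, per the file headers.

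Of the 45220 spots, 41570 carried a locus tag (2143 genes) and 1936 a gene number without a tag (234 genes); 1417 control spots, 108 spots for resistance markers and 189 spots for spike-in RNA were not used as genes. Consecutive gene numbers were taken as neighbours. The 94 probe sequences assigned to more than 1 gene were left out, which left 153 genes without a probe. Signals were corrected with normexp (offset 50) and normalized within arrays by loess on gene spots. Spots marked as population outliers were left out. Spots marked as non-uniform were kept, since this mark covered 60.6% to 69.6% of spots on the arrays of colonised mice, mostly bright ones, against 1.54% and 3.36% on the uninoculated arrays. Saturated spots were kept; up to 3.10% of spots in a channel were saturated. Probes well above background in at least 1 channel on at least 2 of the 4 arrays were kept. Spots were averaged per probe and probes per gene, with a median of 3 probes and 19 spots per gene, leaving 2179 genes, 106 of them without a locus tag.

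Gene log2 ratios were tested with limma (lmFit and eBayes) on the 4 arrays of colonised mice, which shared one estimate of the spread (2 residual degrees of freedom, prior 3.36), with Benjamini-Hochberg adjustment and a threshold of 0.05. Stationary over log phase is the ratio to log phase minus the ratio to stationary phase. The SD given with a log2 ratio is over the 2 arrays; for stationary over log phase the standard error of the fit is given, which does not pair arrays. Fold changes are on the scale of the offset signals and understate changes of dim genes. The uninoculated arrays were tested without centring, since one channel lacks the strain. The simulation of unchanged genes with shared deviations used 1000 draws. The fit was tested on simulated data for 2179 genes with 200 changed: for in vivo vs log phase it recovered 54% of genes changed by 1 on the log2 scale and 100% at 2, for in vivo vs stationary phase 50% and 98%, and for stationary vs log phase 8% and 90%; with no change simulated it called 0 genes. False calls made up 7.81%, 5.43% and 7.50% of the calls in these 3 simulations, above the nominal 5%. All 3 used the same single draw of noise, so these shares do not show whether the error rate lies above 5% on average. The simulation draws arrays independently of each other.

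The named genes follow a rule fixed before the data were examined: those with the largest rises and falls among genes past the threshold with the same sign on both arrays, or the smallest p where none passed, by identifier only and at most 2 per direction because the files do not pair identifiers with names, and for the uninoculated arrays the genes with the highest signal. Lreu23DRAFT_4515, where it is named against log phase, stands for its block, which was singled out after its values were seen. Alternatives fixed beforehand covered the offset, normalization, dim-probe filter, averaging of probes, probes with uninoculated signal, spread, threshold, replicate number as a block, each array left out and the deposited table; leaving out non-uniform spots was added later. The 23 gene lists could not be tested because no gene names were given. R 4.3.3, limma 3.58.1 and the R package data.table (version 1.17.8) were used, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for figures.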

Results

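Gene expression of the gut bacterium Limosilactobacillus reuteri (formerly Lactobacillus reuteri) was measured on 6 custom Agilent microarrays. Each compared a pair of RNA samples, one labelled with the dye Cy3 and one with Cy5. The culture strain was 100-23, a rodent isolate, and the growth protocol names the strain given to the mice 100-23C. On 2 arrays, bacteria recovered from the stomachs of mice 2 weeks after inoculation were set against bacteria growing in log phase in MRS broth, a rich medium for lactobacilli. On 2 further arrays the stomach bacteria were set against a stationary phase culture. The remaining 2 arrays set material from the stomachs of mice that had not been inoculated against log phase RNA and serve as the control for signal that does not come from the strain. The title of the study concerns inactivation of ureC, the gene of a urease subunit; no mutant array was analysed here. The array's annotation gives locus tags or gene numbers and no gene names or products, and none of the 2377 gene identifiers was found in the reference gene table, so genes are given by identifier and the 23 gene lists that had been fixed beforehand, urease among them, matched 0 members.

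Each array carried 45220 spots. Gene probe spots well above background made up 81.7% to 88.1% of the stomach channel and 93.3% to 96.9% of the culture channel on the 4 arrays of colonised mice. Local background was higher in the stomach channel, with medians of 154 to 231 intensity units against 42 to 46 in the culture channel, so dim transcripts were harder to detect there. After filtering, 2179 genes were compared. With 2 arrays per comparison, the number of arrays limits the precision.

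**Figure D1:**
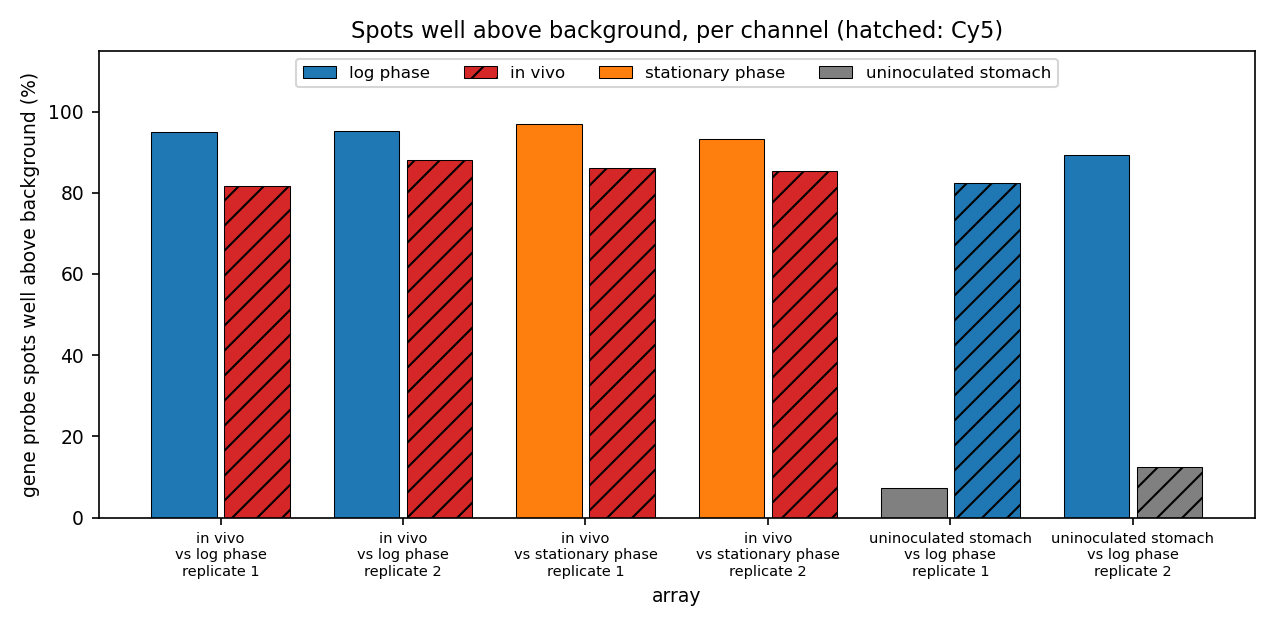
Share of gene probe spots well above background (%, y axis) in each channel of the 6 arrays (x axis), coloured by the RNA in the channel, with Cy5 hatched. The uninoculated stomach channels stand at 7.36% and 12.4%, while the other channels lie between 81.7% and 96.9%.

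The comparison of stomach bacteria with log phase cultures asks which genes differ in expression between life in the mouse stomach and rapid growth in broth. In the stomach, 227 genes were higher and 240 were lower (limma, adjusted p under 0.05). The rises were larger than the falls. Among the called genes, 68 were at least 4-fold higher and 22 at least 32-fold higher, whereas 2 were at least 4-fold lower. Lreu23DRAFT_4464 had the largest rise, with a log2 ratio of 6.93 ± 0.16 (SD, n = 2), or 122-fold (adjusted p = 0.000453, limma). One of its 3 probes has the sequence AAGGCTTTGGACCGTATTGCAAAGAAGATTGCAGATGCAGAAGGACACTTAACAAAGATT. It was followed by Lreu23DRAFT_3554, at 6.59 ± 0.50 (SD, n = 2), or 96.4-fold (adjusted p = 0.000453, limma), which is represented among others by the probe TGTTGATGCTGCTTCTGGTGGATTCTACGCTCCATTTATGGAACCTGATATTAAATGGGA. The stomach signal of this gene was saturated on replicate 2 and not on replicate 1, so its fold and its rank are uncertain.

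Of the 10 genes with the largest rises, 8 belonged to one block of 15 consecutively numbered genes, which includes Lreu23DRAFT_4515. The block is the longest run of genes that were each called and at least 4-fold higher in the stomach than in log phase. That all 15 were higher was therefore fixed by this rule. Their rises ranged from 36.7-fold to 92.4-fold, with adjusted p from 0.000439 to 0.00538 (limma). The median log2 ratio of the block was 5.76 on replicate 1 and 6.04 on replicate 2. Its 15 genes were well above background in the stomach and culture channels on all 4 arrays. Lreu23DRAFT_4515 itself had a log2 ratio of 6.33 ± 0.71 (SD, n = 2), an 80.4-fold rise (adjusted p = 0.000453, limma). All its stomach spots were saturated on replicate 2 and none on replicate 1, so this fold is uncertain as well. Another group of 4 consecutively numbered genes, each called and at least 4-fold higher, holds Lreu23DRAFT_3554 and was 27.5-fold to 96.4-fold higher in the stomach. It is part of a run of 7 called genes with log2 ratios from 1.625 to 6.59.

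**Figure D2:**
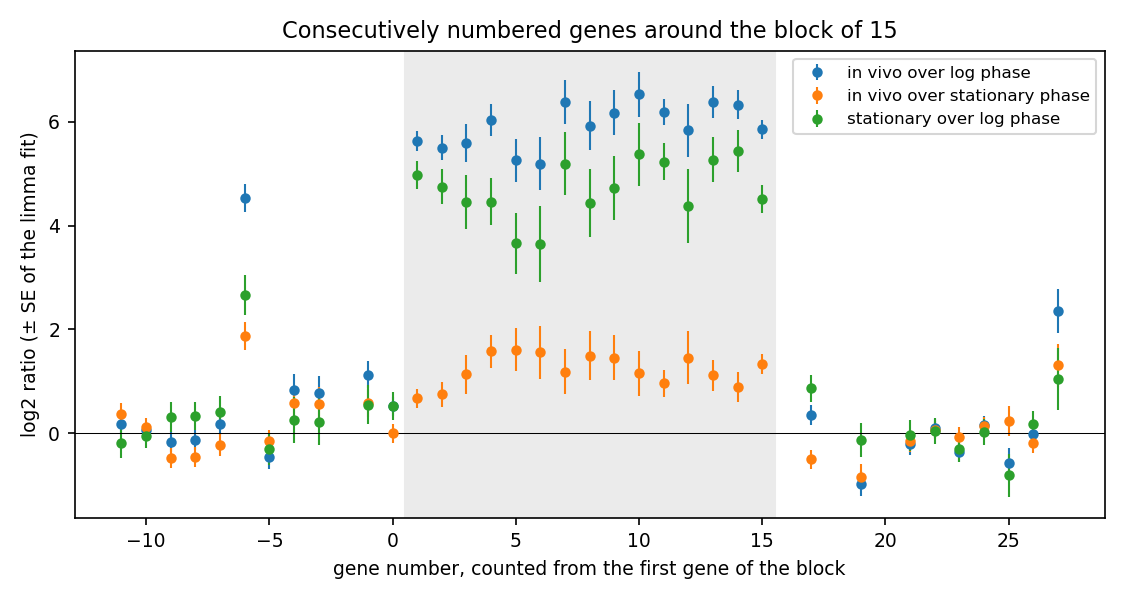
Log2 ratio (y axis, with the standard error of the limma fit) of consecutively numbered genes around the block (x axis, gene number counted from its first gene), for in vivo over log phase, in vivo over stationary phase and stationary over log phase. The 15 genes of the shaded block lie between 5.20 and 6.53 for in vivo over log phase and between 0.67 and 1.61 for in vivo over stationary phase; gaps are numbers with no gene compared.

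The falls relative to log phase were moderate. Lreu23DRAFT_4541 fell most, with a log2 ratio of -2.06 ± 0.57 (SD, n = 2) and an adjusted p of 0.0193 (limma), a 4.16-fold lower level; its probe is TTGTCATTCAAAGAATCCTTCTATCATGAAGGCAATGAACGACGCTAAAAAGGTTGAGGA. Gene 2500070169, which has no locus tag on the array, followed at -2.00 ± 0.75 (SD, n = 2; adjusted p = 0.0174, limma), with the probe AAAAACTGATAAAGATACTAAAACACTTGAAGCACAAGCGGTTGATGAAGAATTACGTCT. The 10 largest falls ranged from -2.06 to -1.87 on the log2 scale. All 467 called genes had the same sign on both arrays, which the test itself requires, since opposite signs give a spread too large for a call. In 454 of them the probes also shared one sign. That count includes genes with 1 probe, for which this holds by definition.

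Stomach RNA carried Cy5 on all 4 arrays, so a gene-specific dye effect cannot be separated from a difference between stomach and culture. The number of called genes fell without log phase replicate 2. On its own 2 arrays this comparison called 714 genes with every log2 ratio unchanged, so that rise came from the spread estimate. The scanner software's processed signals differ in background correction as well as normalization. With them the median of all genes moved to -0.29, and the split was 218 higher and 523 lower in place of 227 and 240. Median centring, which changes the normalization only, gave 265 higher and 315 lower.

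The comparison with stationary phase asks how stomach bacteria differ from cells that have stopped growing in broth. In the stomach, 18 genes were higher and 68 lower (limma, adjusted p under 0.05), and all 86 differed by at least 2-fold. Lreu23DRAFT_3554 had the largest rise here, at 3.35 ± 0.51 (SD, n = 2), or 10.2-fold (adjusted p = 0.0416, limma), and 3 genes of its group of 4 passed the test. Its 3 probes were saturated in the stomach channel on replicate 2 and not on replicate 1, so its fold and its rank are uncertain. Lreu23DRAFT_5115 was 9.18-fold higher, with a log2 ratio of 3.20 ± 1.04 (SD, n = 2; adjusted p = 0.0416, limma). It was at 3.93 without stationary phase replicate 1 and at 2.46 without stationary phase replicate 2, and passed both times. It was 49.8-fold higher against log phase. The block that holds Lreu23DRAFT_4515 had a median log2 ratio of 1.18 here, and 1 of its 15 genes passed the test. That median was 1.96 without stationary phase replicate 1, with 13 genes called, and 0.61 without stationary phase replicate 2, with 0 called; over all alternatives 0 to 15 genes of the block passed. Lreu23DRAFT_4464 had a log2 ratio of -0.21 ± 0.74 (SD, n = 2), which did not pass (adjusted p = 0.627, limma).

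Gene 2500070680 had the largest fall against stationary phase, at -2.73 ± 0.82 (SD, n = 2; adjusted p = 0.0443, limma), a 6.63-fold lower level in the stomach; without stationary phase replicate 2 it was at -2.15 and did not pass (adjusted p = 0.0605, limma). Lreu23DRAFT_3973 was 5.83-fold lower, at -2.54 ± 0.26 (SD, n = 2; adjusted p = 0.0416, limma). The stationary phase signal was saturated on both arrays for 1 of its 2 probes, so the fold is uncertain. Lreu23DRAFT_4541 and 2500070169, the largest falls against log phase, were also lower than in stationary phase, at -2.17 and -2.02.

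This comparison depended on single arrays: far fewer genes passed without stationary phase replicate 2, and more without stationary phase replicate 1. The number of calls also depended on the spread estimate. On the 2 stationary phase arrays alone 409 genes passed, with every log2 ratio unchanged. Leaving out the spots that the scanner software marked as non-uniform left 1132 genes and 0 calls (limma, with 216 genes at an unadjusted p under 0.05), median centring gave 99 higher and 174 lower, and scaling between arrays gave 156 higher and 291 lower. With that scaling, 347 genes were called against log phase, so which comparison had more calls depended on the normalization.

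**Figure D3:**
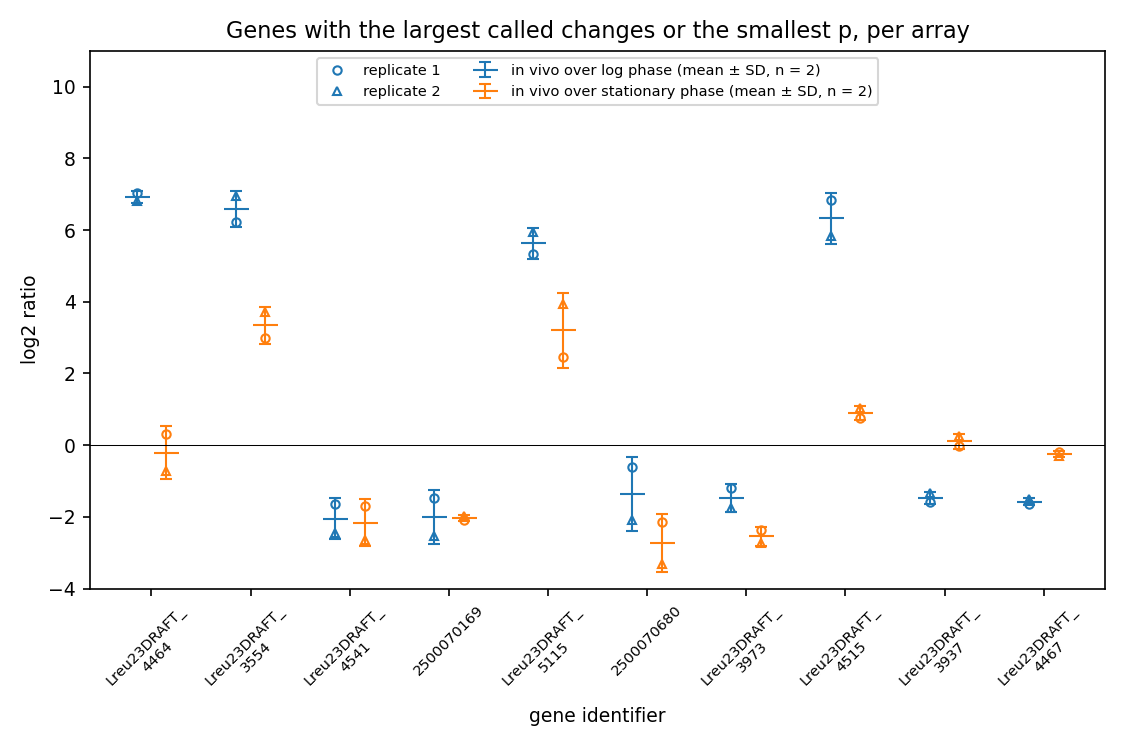
Log2 ratio (y axis) of each gene named for the comparisons of stomach, log phase and stationary phase (x axis), for in vivo over log phase and in vivo over stationary phase; symbols are single arrays, dashes with bars the mean ± SD (n = 2). Lreu23DRAFT_4464 lies at 6.93 against log phase and at -0.21 against stationary phase.

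The difference between the ratios to the 2 cultures gives stationary over log phase, a contrast in which a gene-specific dye effect cancels. The labels do not say whether the stomach RNA of both sets of arrays came from the same pools. It is also the test of whether the in vivo ratio differed between the cultures. With the arrays taken as independent, it called 26 genes higher in stationary phase and 0 lower (limma, with 246 genes at an unadjusted p under 0.05). That split depended on this choice: with the replicate number as a block, given further below, genes were called lower too. Lreu23DRAFT_4464 was 141-fold higher in stationary than in log phase, at a log2 ratio of 7.14 ± 0.40 (SE of the fit; adjusted p = 0.00563, limma). Lreu23DRAFT_4515 followed at 5.44 ± 0.40 (SE of the fit), or 43.5-fold (adjusted p = 0.00815, limma), from the 1 probe of the gene with a value on all 4 arrays. Its stomach spots were saturated on replicate 2 of both comparisons, so this fold and its rank are uncertain. The block around it held 9 of the 10 largest rises and 11 of the 26 calls. The estimates for its 15 genes, called or not, ran from 12.5-fold to 43.5-fold higher in stationary phase. The lowest, for 2500070109, did not pass (adjusted p = 0.133, limma). Lreu23DRAFT_3554 was 9.48-fold higher in stationary than in log phase (adjusted p = 0.0303, limma); its 3 probes were saturated in the stomach channel on replicate 2 of both comparisons, so this fold is uncertain too.

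The lower genes with the smallest p were Lreu23DRAFT_3937, at -1.58 ± 0.26 (SE of the fit; adjusted p = 0.0772, limma), and Lreu23DRAFT_4467, at -1.34 ± 0.24 (SE of the fit; adjusted p = 0.0995, limma), neither of which passed the test in the main fit. Both passed with the replicate number as a block, as given further below. With the arrays taken as independent, as in the main fit, Lreu23DRAFT_3937 did pass with median centring (adjusted p = 0.00447, limma), with the median of the probes (0.0459), without log phase replicate 2 (0.0286) and without stationary phase replicate 1 (0.0484). The count was 85 without log phase replicate 2, 88 without log phase replicate 1, 58 without stationary phase replicate 1 and 47 without stationary phase replicate 2. Median centring gave 55 higher and 8 lower.

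The log2 ratios of the 2 in vivo comparisons were correlated across the 2179 genes (Pearson r = 0.68, Spearman rho = 0.74; genes are not independent replicates). Both sets may share stomach RNA, and unchanged genes simulated with the observed shared deviations gave r = 0.73. Their covariance was 0.428, against a simulated 0.064. Both comparisons called the same 15 genes higher and the same 49 lower, with 1.88 and 7.49 for independent lists, and 0 genes went opposite ways, with 9.07 for independent lists. Lreu23DRAFT_3554 and Lreu23DRAFT_5115 were among the genes higher in both, and Lreu23DRAFT_4541 and 2500070169 among those lower in both. Part of the excess may come from the shared stomach RNA and the shared dye.

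**Figure D4:**
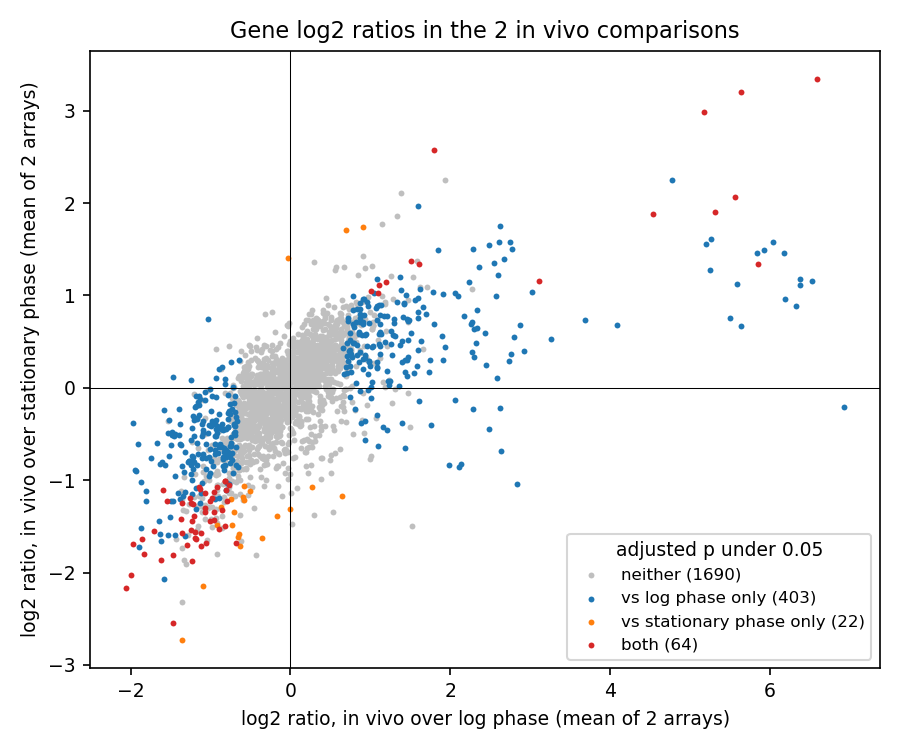
Mean log2 ratio of each of the 2179 genes for in vivo over log phase (x axis) and in vivo over stationary phase (y axis), coloured by the comparison in which the gene had an adjusted p under 0.05. The genes with the highest ratios to log phase, up to 6.93, reach at most 3.35 against stationary phase.

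The uninoculated arrays ask how much signal on the bacterial probes comes from stomach material without the strain. In the uninoculated channel, 293 of 2224 genes (13.2%) had a probe well above background on both arrays, against 1930 genes (86.8%) in the log phase channel. All probes were above background on both arrays for 39 genes (1.75%), and 392 of 7223 single probes (5.43%) were. Log phase signal was higher for 2185 genes and uninoculated signal for 0 (limma without centring, adjusted p under 0.05), with a median log2 ratio of -2.70 for uninoculated over log. The size of that gap depends on the offset added to the signals, and the median was -6.13 with offset 0. Single probes went the other way: 7 of 7223 probes were brighter with uninoculated RNA on both arrays, 2 of them by at least 2-fold. Gene 2500070968, without a locus tag, had the highest uninoculated signal, at 19959 and 19397 intensity units against 3280 and 3869 for log phase. Its 2 probes disagreed, with log2 ratios of -5.84 and 3.50. Its log2 ratio of in vivo to log phase was 0.01 (adjusted p = 0.982, limma). Gene 2500069815 came next, at 3323 and 22995 units on replicates 1 and 2, against 50594 and 44568 for log phase. The 5 genes with the highest uninoculated signal all lacked a locus tag, and none of them passed the test of stomach against log phase, with log2 ratios of 0.01 to 0.72. Of these, 2500071249 (427 and 15860 units) and 2500069814 (674 and 14300 units) ranked there mainly through replicate 2. Among all genes, 13.9% of those without a tag and 13.1% of those with one had uninoculated signal. The share of genes counted as detected rose to 55.8% with the scanner software's flag for a positive and significant signal and to 64.8% for signal above the highest 5% of negative controls.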

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

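The tests of the dye effect and of the normalization below were chosen after the results were seen. The ratio of stomach to culture differed between the 2 cultures for 26 genes, which is the test of stationary over log phase (limma). The block of 15 consecutively numbered genes around Lreu23DRAFT_4515 carried 11 of them and stood a median 61.0-fold higher in the stomach than in log phase. A gene-specific dye effect would cancel in stationary over log phase, yet the block's median log2 ratio there was 4.72, with a lowest value of 3.64. Stomach RNA from other sources is argued against by the uninoculated arrays, where the block's median log2 ratio of uninoculated over log phase was -0.95 and its highest value -0.50. Normalization moved the block's median against log phase to 5.04 at the lowest. All 15 genes were well above background in log phase too. Their measured level was nevertheless lower in log phase than in stationary phase (11 of 15 called) and than in the stomach. Against the stomach 15 of 15 were called, which membership in the block required. What stays open, untested, is the reason for the lower level in log phase, such as the growth phase of the culture. The block was found and tested on the same data.

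Probes outside the gene set also gave signal. Spots for the spike-in sequence RNASPIKE4 were well above background for 36.1% of spots on average in the stomach channel, which always carried Cy5. In the culture channel of the same 4 arrays the share was 0% to 18.5%. It was 5.56% on average in the uninoculated channel, which was on the other slide and read on another scanner. Spots for RNASPIKE2 were well above background for 33.3% in the uninoculated channel, whichever dye it carried. In the log phase channel of the same arrays the shares were 0% and 11.1%.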

How the results depend on the processing

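The named genes gave 190 values under the alternatives: 180 kept their direction and side of the threshold, 4 no longer passed, 6 newly passed and 0 changed sign. The 4 were 2500070169 against log phase with scaling between arrays, and, against stationary phase, Lreu23DRAFT_3554 without non-uniform spots and 2500070680 with no dim-probe filter or without stationary phase replicate 2. Many of the 190 values stayed the same by construction, where only the spread, threshold, replicate block or an array of the other comparison changed. The deposited table holds the ratios of the processed signals, and the genes were picked as extremes of the same data. The 180 are therefore not independent checks. For in vivo vs log phase (467 called), the count was 741 with the scanner's processed signals and with the deposited table, 714 on its own 2 arrays, 301 with at least 2-fold, and 192 without non-uniform spots (chosen after seeing the data; 1132 genes tested). For in vivo vs stationary phase (86) it was 273 with median centring, 521 with processed signals, 523 with the deposited table, 447 with scaling between arrays, 147 with both channels above background on all 4 arrays, 409 on its own 2 arrays and 0 without non-uniform spots. For stationary vs log phase (26) it was 63 with median centring and 8 without non-uniform spots. The medians of all genes moved to -0.29 and -0.23 with processed signals and to -0.30 and -0.24 with the deposited table, against log and stationary phase. On its own 2 arrays, or without an array of the other comparison, each comparison kept every log2 ratio. Those counts changed through the spread estimate alone. A minimum fold can only take calls away. The cause of the other shifts was not tested. Leaving out each array gave 247 to 714, 6 to 409 and 47 to 88 calls; an array left alone is assumed to vary like the others. The median of the 15-gene block lay between 5.04 and 6.45 against log phase (8 to 15 genes called, 8 being all that were left without non-uniform spots), 0.61 and 1.96 against stationary phase (0 to 15) and 3.79 and 5.29 for stationary over log phase (6 to 15).

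With the replicate number as a block the counts were 1342 (630 higher, 712 lower), 1108 (489 and 619) and 349 (224 and 125, in place of 26 and 0), and Lreu23DRAFT_3937 and Lreu23DRAFT_4467 passed as lower in stationary phase. The block takes replicate deviations shared by both in vivo comparisons out of the error, so 1342 and 1108 ignore that spread. The labels do not say that a number marks shared RNA, so pairing was not assumed. Replicate differences of the 2 comparisons had r = 0.73 across genes (0.39 in Cy5, 0.28 in Cy3, and 0.73 without GC and signal trends).

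The correlation of the in vivo comparisons was 0.50 and 0.57 between arrays of different number, and 0.59 to 0.72 with an array left out. The uninoculated share (13.2%) was 55.8% with the positive and significant flag, 64.8% above negative controls, and 14.4% to 19.9% on single arrays. With offset 0 the median log2 ratio of uninoculated over log moved from -2.70 to -6.13. The gene list alternatives, with 0 members, were not run. Higher stomach channel background limits dim genes.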

Other observations

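The tests of uninoculated signal among the higher genes and of bright genes below were chosen after the results were seen. Some called genes carried consecutive numbers. Of the 227 genes higher in the stomach than in log phase, 78 lay in 17 runs of at least 3 such genes. Of the 240 lower genes, 60 lay in 15 runs. Besides the block around Lreu23DRAFT_4515, the run of 7 genes that includes the group of 4 with Lreu23DRAFT_3554 had a median 27.5-fold rise. A further run of 7 was raised by a median of 5.06-fold. The longest run of lower genes, also 7, had a median log2 ratio of -1.10. In the comparison with stationary phase, 3 of the 18 higher genes and 3 of the 68 lower genes lay in such runs. Log2 ratios of the 2061 neighbouring pairs had r = 0.60 against log phase, 0.45 against stationary phase and 0.57 for stationary over log phase, across genes. In the difference between the 2 replicates, a difference between stomach and culture that both replicates share cancels. This replicate difference was itself correlated between neighbours, with r = 0.44 for the log phase arrays and 0.57 for the stationary phase arrays. Deviations of single replicates are therefore shared by neighbours, and those of the arrays cannot be told apart from those of the stomach pools and cultures. A shuffle of the gene order is thus no valid test of the runs, and neither the runs nor these correlations show joint regulation.

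The ratios to log phase spread more widely over genes than the ratios to stationary phase, with SDs of 0.96 and 1.08 on the log phase arrays and 0.51 and 0.86 on the stationary phase arrays. This difference was not tested. Probe GC content had a Spearman correlation with the log2 ratio of 0.23 against log phase and 0.27 against stationary phase, and of -0.02 for stationary over log phase, across genes.

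Material in the stomach other than the strain might raise genes in the stomach channel. Genes with uninoculated signal made up 13.2% of those higher than in log phase and 13.3% of all genes compared, an odds ratio of 0.99 (95% interval 0.64 to 1.50). This interval and the one below take genes as independent, although neighbours were correlated, so they may be too narrow. Only the flag for signal well above background was used, and other criteria counted far more genes as having uninoculated signal. Within these limits, the near-equal shares argue against such material as the source of the rises against log phase as a set. Of the 240 lower genes, 17 had such signal. The median log2 ratio was 0.02 for genes with it and -0.06 for the rest, so a small lift of ratios was not excluded. Against stationary phase 5 of the 18 higher genes had such signal, an odds ratio of 2.53 (0.70 to 7.63), which leaves the question open there.

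The labels name different strain designations for the mice and the cultures, and genes absent from the strain given to mice, bright genes or dim, could appear as genes with culture signal and none in the stomach. There were 3 runs of at least 3 consecutively numbered genes that were well above background in the cultures and not in the stomach on all 4 arrays. Their 11 genes were dim in culture, with a median signal of 150 and at most 211 units, and their log2 ratios lay between -0.74 and 0.05, so the higher Cy5 background keeps absence and low expression from being told apart. Among bright genes, with a culture signal above 500, there were 0 such runs, and 1 of 1788 was not above background in the stomach on any array, which argues against the loss of a set of genes expressed at that level.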
